A study of Mus musculus with 6 samples.

How the data were processed

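Oocytes arrested at the germinal vesicle stage, before the first meiotic division resumes, were profiled from wildtype mice and from mice homozygous for a Brwd1 mutation, on a mixed background of B6 and C3H. Per the labels' protocols, the females were 2 to 6 months old and had been injected with 5 IU equine chorionic gonadotropin, a hormone that stimulates follicle growth, 44 h before the oocytes were collected. Each sample was a pool of 100 oocytes, and each group had 3 samples, named here by the replicate number in the labels. The labels do not say that the pools came from separate animals, so p-values measure only the spread between these samples, which may be technical.

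Per the labels' protocols, RNA was isolated with the Qiagen RNeasy Micro kit, 1 ng of total RNA was amplified with the NuGEN Ovation Pico whole-transcriptome system, and the cDNA was fragmented and labelled with biotin. Each of the 6 samples was hybridised to its own Affymetrix mouse Gene ST array, read in 1 colour. The deposited values are log2 values. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.1 and RMA, which corrects background, forces the arrays to a common distribution and summarises the probes of each probe set. The table names no scale itself. Its values, given to 2 decimals, have quantiles that nearly coincide between arrays, with small offsets between the groups. This normalization brings the overall distributions of the arrays close together, so a change in the total RNA per oocyte cannot be seen. A log2 difference here is relative to the other transcripts on the array. Amplification from little RNA and the compression of RMA near background make fold differences of dim probe sets smaller than the true ones. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

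The table held 35556 probe sets. The array annotation gave exactly 1 gene symbol for 21789 of them, several for 1621 and listed none for 12146. Gene identifiers of 21698 of the single-symbol probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 of these symbols differed. No gene was named from a probe set with several symbols. All 23410 probe sets with at least 1 symbol were tested without a filter on level.

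Mutant minus wildtype differences were fitted on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), over all 6 arrays and without covariates. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Standard errors (SE) and 95% confidence intervals are those of the limma fit. Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, on the brightest probe set of each gene, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, another set test of limma, were run as alternatives. Within each list, limma p-values were also adjusted over the list alone, which does not correct for the number of lists. Genes within 20 Mb of Brwd1, located with the RefSeq gene table, were compared with all other located genes by Fisher's exact test, two-sided, because a mutation kept on a mixed background carries flanking DNA of 1 strain.

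Before the data were examined, 26 lists were fixed, covering oocyte functions, chromatin, stress, metabolism and the other cell types an oocyte pool could hold (granulosa and cumulus cells, theca and stroma, and blood, immune and endothelial cells). The 25 lists with at least 5 measured members were tested, and the list of genes encoded by mitochondrial DNA was not. The rule for the genes named was fixed at the same time. It took Brwd1, then up to 12 rises and 12 falls with the largest log2 difference among single-symbol probe sets past the threshold whose groups did not overlap, leaving out predicted genes, small RNA genes and olfactory or vomeronasal receptors. Empty places went to the smallest unadjusted p-values in that direction. Up to 4 members of each list with the smallest p-values were also eligible.

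The alternatives tried were the replicate number as a block, filters on dim probe sets (above the median and above the 25th percentile), normalizing the values again by quantile, cyclic loess or median centring, eBayes with trend and robust settings, array weights, all probe sets of the table, the mean of each gene's probe sets, other thresholds, other windows around Brwd1, and leaving out each array in turn. Counting repeated probe sets once and an unadjusted threshold around Brwd1 were added after seeing the data.

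The procedure was tested on simulated data in which 200 of 23410 probe sets were changed by known amounts, in 5 runs for the mutant against wildtype comparison. It recovered 44.4% of differences of 0.5 on the log2 scale, 86.0% of those of 1, 98.4% of those of 2 and 100% of those of 4, and a mean of 5.17% of its calls were false. With no list shifted, 0 lists passed, and a list shifted by 0.1 passed in 5 of 5 runs. These simulations drew noise independently for each gene. They also changed 50 probe sets by each size, and many large changes make the adjusted threshold easier to pass than in the real data. There, 53 probe sets differed by at least 1 and 4 of these passed, so the simulated shares do not carry over. In the real data the median SE was 0.0811 and the median smallest difference that could be called was 0.69 on the log2 scale. The number of arrays limits the precision.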

Results

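The comparison asked how loss of normal Brwd1, which encodes a protein with bromodomains and WD repeats, affects the transcripts stored in mouse oocytes. Levels were measured by microarray in 3 wildtype and 3 homozygous Brwd1 mutant samples of 100 germinal vesicle stage oocytes each. The median level over all probe sets was 4.71, 4.70 and 4.69 on the log2 scale in wildtype 1, 2 and 3. In mutant 1, 2 and 3 it was 4.71, 4.79 and 4.77. The upper quartile was 7.12, 7.10 and 7.11 in the wildtype and 7.09, 7.04 and 7.07 in the mutant samples. Offsets of this size are comparable to the list medians given below. Pearson's r across probe sets was 0.995 to 0.996 between arrays of a group and 0.993 to 0.995 between groups, where probe sets are not independent replicates. The leading principal component held 37.8% of the variance and separated the genotypes, and wildtype 3 stood apart from the other arrays on the next, which held 19%.

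Brwd1 itself was lower in every mutant sample. Its level was 8.91, 9.08 and 8.98 in the wildtype samples and 4.41, 4.56 and 4.50 in the mutant samples. The log2 difference was -4.50 (SE 0.071, n = 3 per group), 22.6-fold on the measured values (limma, Benjamini-Hochberg adjusted p = 2.2e-06). For scale, the 1377 probe sets of olfactory and vomeronasal receptors, taken as a guide to background, had a median level of 3.16 and a 95th percentile of 4.48. The mutant mean of 4.49 lies at that percentile, so the measured fold is read as a lower limit, without an interval. The same holds for other genes with a group mean at or under it, among them Gca and Gm6377, at 3.94 and 4.06 in the mutant samples. The labels do not say which part of the transcript the mutation affects.

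Beyond Brwd1, 18 named genes passed the threshold, with differences of modest size. Of the 8 rises, Meioc, which maintains meiotic prophase in germ cells, had the largest, from 6.28 ± 0.21 to 7.39 ± 0.13 (SD, n = 3 per group), a log2 difference of 1.11 (SE 0.120; limma, adjusted p = 0.0351). Hmox1, the heme-degrading enzyme heme oxygenase 1, rose by 1.01 from 5.53 (SE 0.0889; limma, adjusted p = 0.0297), and Trp73, a relative of p53, rose by 0.93 from 6.92 (SE 0.0910; limma, adjusted p = 0.0297). Klk14, a secreted serine protease, rose by 0.87, Bmerb1 by 0.79, Plek, which encodes pleckstrin, by 0.66, Ifitm3, an interferon-induced membrane protein, by 0.64 and Caln1, a calcium-binding protein, by 0.53. Of the 10 falls besides Brwd1, Aamdc had the largest, from 5.81 ± 0.15 to 4.71 ± 0.16 (SD, n = 3 per group), a log2 difference of -1.10 (SE 0.107; limma, adjusted p = 0.0297).

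The other falls, as log2 differences, were -0.97 for Gca, a calcium-binding protein, -0.74 for the zinc-finger gene Zfp770, -0.69 for Rps4l, a relative of ribosomal protein S4, -0.68 for Mxra8 and -0.66 for Cyct, the cytochrome c of testis. Igf1r, the receptor of insulin-like growth factor 1, fell by 0.62, Pcbd1, which recycles the cofactor tetrahydrobiopterin, by 0.61, the zinc-finger gene Zfp560 by 0.59 and Derl3, which takes part in degradation of misfolded proteins of the endoplasmic reticulum, by 0.52. Rps4l had a second probe set at -0.30 (limma, adjusted p = 0.171), and signal from ribosomal protein genes with similar copies is uncertain. The adjusted p-values of the 18 genes lay between 0.0297 and 0.0489 (limma, Benjamini-Hochberg), and their folds between 1.45 and 2.16 for rises and between 1.43 and 2.14 for falls. The genes next in rank did not pass: Serpinc1 at 0.55, Upb1 at 0.71, Shank2 at 0.56, Foxn3 at 0.57, Sult5a1 at -0.67 and Fbxw13 at -0.93 had limma adjusted p-values of 0.0535 to 0.0599. For Shank2 and Foxn3, which have 3 and 2 probe sets, the mean of the gene's probe sets differed by 0.30 in both.

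In all, 32 of 23410 probe sets passed, 9 higher and 23 lower in the mutant, and 4 of them differed by at least 1 on the log2 scale. The higher share was 28.1%, against 16.7% after median centring, 34.5% after quantile normalization again and 32.4% after cyclic loess. Among the 21 single-symbol probe sets that passed, 9 were higher and 12 lower. The 32 include 2 predicted genes, 3110040M04Rik at 0.60 and Gm6377 at -0.70. They also include 11 probe sets that each list the same 9 predicted genes and hold only 2 different sets of values, 7 at -0.90 and 4 at -0.91. At an unadjusted p under 0.05, limma gave 3443 probe sets, 1710 higher and 1733 lower, where 1170.5 were expected by chance, and the groups did not overlap at 19.7% of probe sets, where chance gives 10%.

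Which genes pass besides Brwd1 depends on the set of probe sets tested and on single samples. Only Brwd1 passed when repeated probe sets were counted once (the next limma adjusted p was 0.0503), a check chosen after seeing the data, or when all 35556 probe sets were tested (0.0728). The count was also 1 without wildtype 1, wildtype 2 or mutant 1, 3 without mutant 2, 10 without mutant 3 and 18 without wildtype 3, and of the 19 genes with Brwd1 counted, Meioc and Trp73 passed beside Brwd1 in 1 of these 6 omissions, that of wildtype 3.

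**Figure D1:**
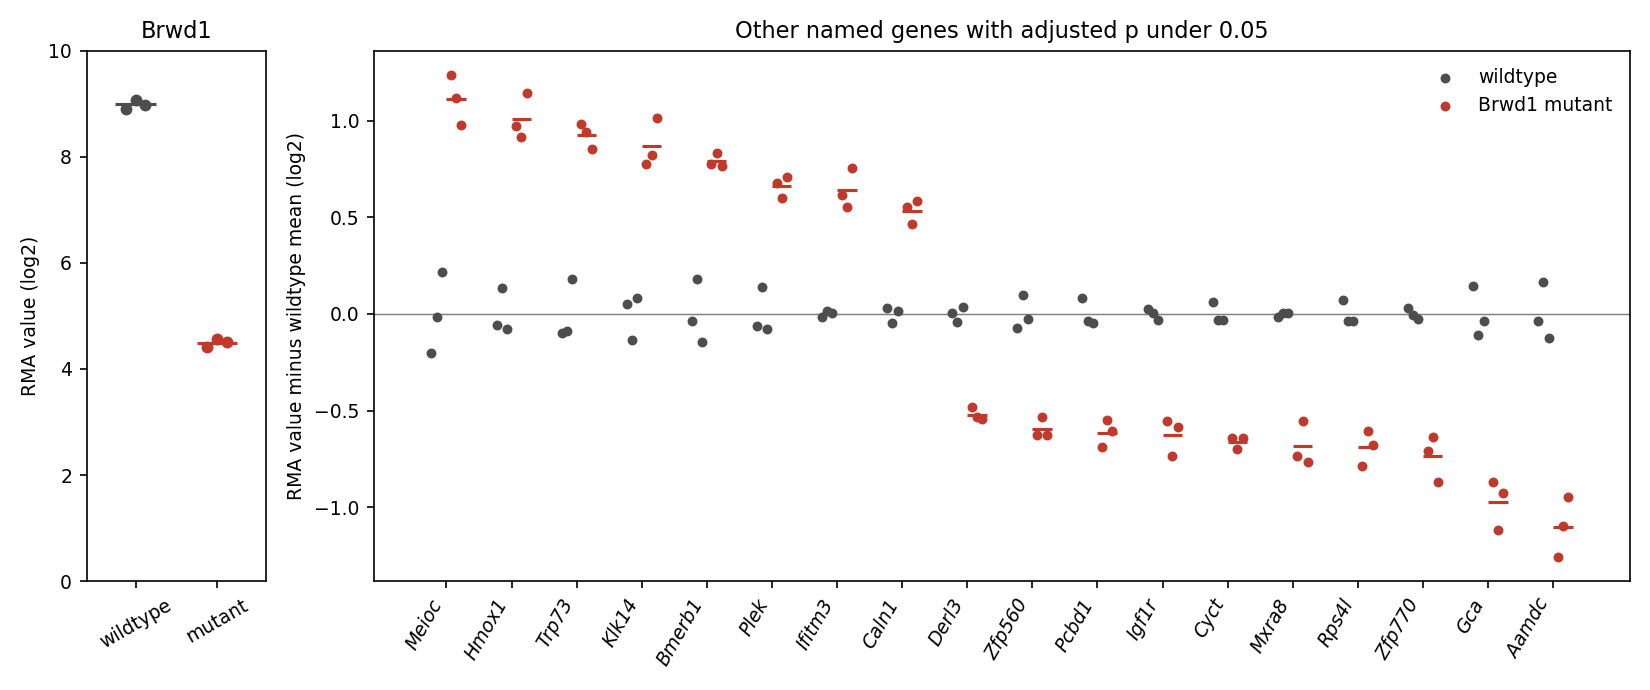
Left, the RMA log2 level of Brwd1 in each of 3 wildtype (grey) and 3 mutant (red) samples, with lines at the group means of 8.99 and 4.49. Right, the level of each of 18 other named genes minus its wildtype mean, on the log2 scale, with 1 point per sample and a line at the mutant mean. For every gene shown, the 3 mutant points lie on one side of the 3 wildtype points.

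Genes close to Brwd1 were examined because flanking DNA of 1 strain can travel with a mutation on a mixed background. Within 20 Mb of Brwd1, 0 of 140 located genes passed the threshold, against 20 of 19720 elsewhere (Fisher's exact test, two-sided, p = 1; 95% confidence interval of the odds ratio 0 to 28.8). With so few genes called anywhere, that comparison could show little either way. At a limma unadjusted p under 0.05 the shares were 14.3%, or 20 genes, near Brwd1 and 14.9% elsewhere (Fisher's exact test, two-sided, p = 1; odds ratio 0.954, 95% confidence interval 0.562 to 1.54). Among them was Hmgn1, a nucleosome-binding protein, at -0.23 (limma, adjusted p = 0.272). Without mutant 3, 1 of the nearby genes passed, Fam3b (Fisher's exact test, p = 0.0141). Fam3b, which encodes a secreted protein and is named here after its values were seen, was at 7.21, 7.32 and 7.15 in the wildtype samples and at 4.47, 4.05 and 7.09 in mutant 1, 2 and 3. Its log2 difference was -2.02 (SE 0.729; limma, adjusted p = 0.281) over all arrays and -2.97 without mutant 3 (limma, adjusted p = 0.00914), where both mutant levels lie under the background guide of 4.48 and the size is a lower limit.

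Of the lists fixed before the data were examined, 5 of 25 passed with limma's camera, 4 lower and 1 higher in the mutant, and 0 passed with an estimated correlation or with fry. The median of the 81 nuclear genes of oxidative phosphorylation was -0.063 on the log2 scale (camera, adjusted p = 0.000206; adjusted p = 0.584 with an estimated correlation), with 61 members lower and 20 higher. Over all genes 0 of them passed, and adjusted over the list alone 1 fell, Cox7a1, a subunit of cytochrome c oxidase, at -0.77 (limma, adjusted p = 0.0296 over the list, 0.104 over all genes). Ndufs4 was at -0.22, Cox4i2 at -0.45 and Cox8c, a testis form, at 0.73. For 58 cytosolic ribosomal proteins the median was -0.045 (camera, adjusted p = 0.0101; adjusted p = 0.622 with an estimated correlation), 43 members were lower, and Rps4l was the 1 gene that fell both over all genes and adjusted over the list alone.

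The median of 50 DNA repair genes was -0.082 (camera, adjusted p = 0.00336; adjusted p = 0.584 with an estimated correlation), and 33 members were lower. No member passed over all genes or adjusted over the list alone. The smallest p-values belonged to the mismatch repair gene Msh3 at -0.47, Xrcc6, a subunit of Ku, at -0.32, the ubiquitin ligase Rnf168 at -0.24 and the DNA ligase Lig3 at -0.32 (limma, adjusted p = 0.0597 over the list for Msh3). The median of 44 histone genes was -0.085 (camera, adjusted p = 0.00964; adjusted p = 0.584 with an estimated correlation), 30 members were lower, and 0 passed over all genes or adjusted over the list alone. H2ax was at -0.27, H2az2 at -0.26, H2ac1 at -0.24 and H4c9 at -0.23, and histone genes with near-identical copies are uncertain.

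Markers of blood, immune and endothelial cells were higher, with a median of 0.075 over 18 genes (camera, adjusted p = 0.0339; adjusted p = 0.584 with an estimated correlation). Their median level was 4.44 in wildtype and 4.52 in mutant samples, near the background guide of 4.48. Bins of all genes with mean levels of 4.41 and 4.92 had medians of 0.067 and 0.077, so a shift of this size is not particular to these markers. Of the 18 markers, 16 were higher and 2 lower, and 0 passed over all genes or adjusted over the list alone. C1qb, a subunit of complement C1q made by macrophages, was at 0.90 (SE 0.210; limma, adjusted p = 0.162), from 6.00 ± 0.43 to 6.90 ± 0.18 (SD, n = 3 per group), C1qa was at 0.18 and Csf1r at 0.19. The other markers of follicle cells did not pass. The 29 genes of granulosa and cumulus cells had a median of 0.050 (camera, adjusted p = 0.399), with Gata4 at 0.29, Ptgs2 at -0.57 and Has2 at 0.49. That median ran from 0.0067 to 0.11 without 1 array and reached 0.15 in another setting, without passing. The 18 genes of theca and stroma had a median of 0.038 (camera, adjusted p = 0.814). In both, 0 members passed over all genes or adjusted over the list alone.

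After cyclic loess, 4 of the 5 lists no longer passed, with medians and camera adjusted p-values of -0.041 and 0.122 for oxidative phosphorylation, -0.066 and 0.107 for DNA repair, -0.019 and 0.398 for ribosomal proteins and 0.025 and 0.252 for immune markers, while histone genes stayed at -0.11 and 0.0229. After median centring, which moved the median of all probe sets from 0.010 to -0.047, all 5 passed by camera, at -0.12 for oxidative phosphorylation, -0.14 for DNA repair, -0.10 for ribosomal proteins, -0.14 for histone genes and 0.018 for immune markers. Oxidative phosphorylation passed under each of the 6 omissions of an array, with medians from -0.083 to -0.047. The call of DNA repair ended without mutant 2, at a median of -0.023 (camera, adjusted p = 0.0627). Histone genes did not pass without wildtype 1, at -0.049 (camera, adjusted p = 0.0636), or mutant 1, at -0.067 (0.122), but were at -0.17 without wildtype 2, -0.15 without mutant 3 and -0.25 among probe sets above the median level. Ribosomal proteins did not pass without wildtype 1, at -0.034 (camera, adjusted p = 0.136), or mutant 2, at -0.041 (0.0544). Immune markers did not pass without wildtype 2, at 0.098 (camera, adjusted p = 0.156), wildtype 3, at 0.054 (0.0524), mutant 1, at 0.10 (0.0743), or mutant 3, at 0.067 (0.141). Above the median level the other lower lists did not pass, at -0.073 for oxidative phosphorylation (camera, adjusted p = 0.0892), -0.082 for DNA repair (0.1996) and -0.047 for ribosomal proteins (0.259).

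**Figure D2:**
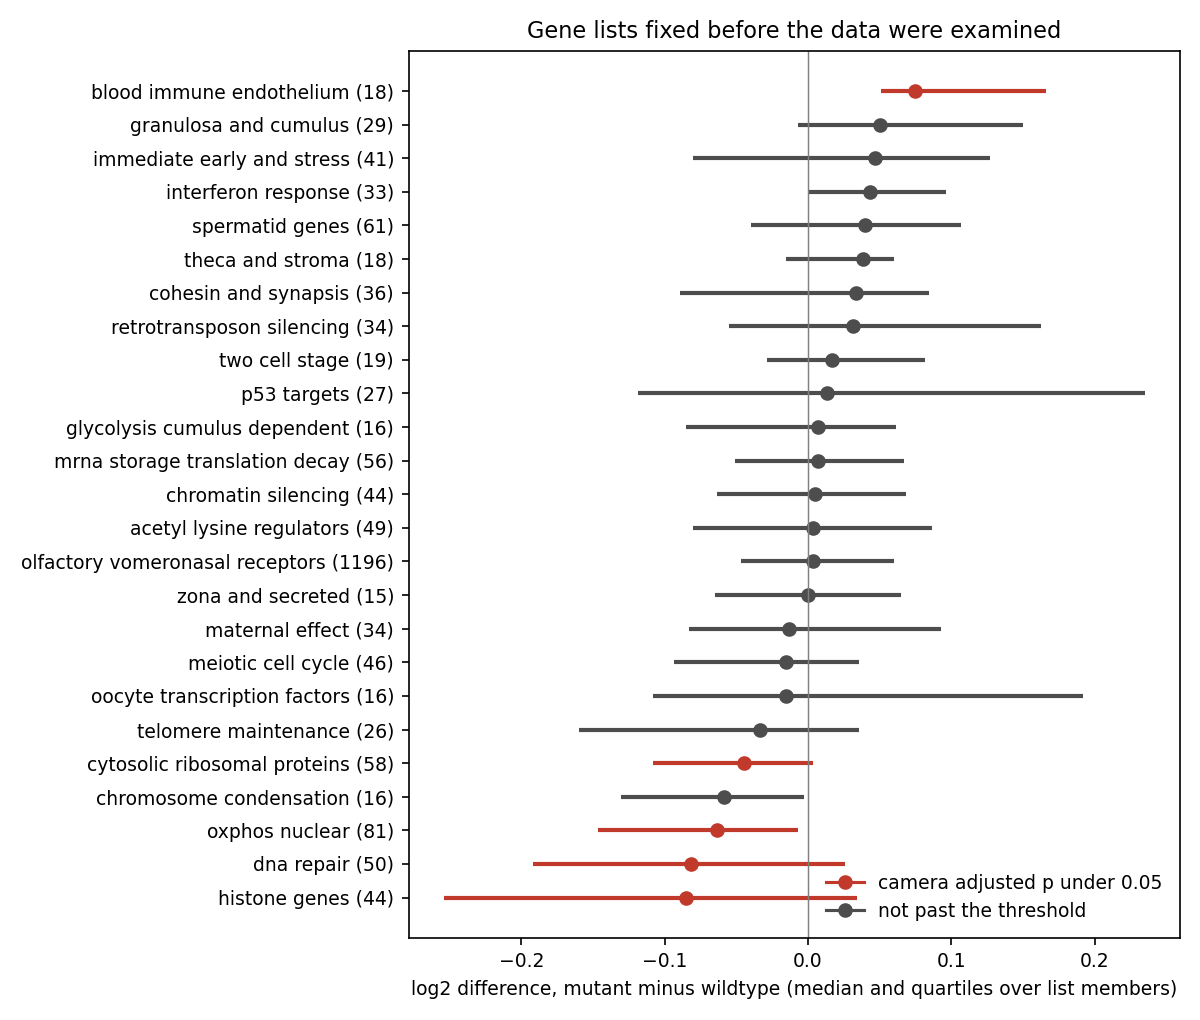
Log2 difference, mutant minus wildtype, over the members of each of 25 gene lists, with the number of measured members in parentheses. Points are medians and lines run between the quartiles. Red marks the 5 lists past the threshold with camera at the preset correlation, of which histone genes had the lowest median, -0.085, and blood, immune and endothelial markers the highest, 0.075.

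Transcripts that define the oocyte showed no list call. The 15 zona pellucida and secreted factors had a mean difference of -0.0073 (camera, adjusted p = 0.929), with Zp1 at 0.083, Gja4 at -0.077 and Kit, the stem cell factor receptor, at -0.23. The 34 maternal effect genes, whose products are needed by the early embryo, had a median of -0.013 (camera, adjusted p = 0.929), with Sebox at -0.38 and Pou5f1 at -0.31. In both lists 0 members passed over all genes or adjusted over the list alone. Among 16 oocyte transcription factors (camera, adjusted p = 0.929), 0 passed over all genes and 1 rose adjusted over the list alone, the heat shock factor gene Hsf2, at 1.09 (limma, adjusted p = 0.0147 over the list, 0.122 over all genes). The median of that list was -0.015 and its mean 0.070.

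Lists of meiosis and chromosome structure did not pass either, and 0 of their members passed over all genes or adjusted over the list alone. Meiotic cell cycle genes (46) had a median of -0.015 (camera, adjusted p = 0.178), with Ccnb2 at -0.18 and Mad2l1 at -0.20. Cohesin and synapsis genes (36) had a median of 0.033 (camera, adjusted p = 0.929), with Sycp3, a component of the synaptonemal complex, at 0.90 (SE 0.227; limma, adjusted p = 0.186). Chromosome condensation genes (16) had a median of -0.058 (camera, adjusted p = 0.164), with Ncapg at -0.20, and telomere maintenance genes (26) a median of -0.033 (camera, adjusted p = 0.168), with Nop10 at -0.37. The telomere median ran from -0.069 to 0.0175 without 1 array, so its sign was not stable.

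Chromatin regulators gave no single-gene calls over all genes and few adjusted over the list alone. Of 49 regulators of acetylated lysine, 0 passed over all genes and 1 fell adjusted over the list alone, the bromodomain gene Brd9, at -0.39 (limma, adjusted p = 0.0309 over the list, 0.122 over all genes), and the list median was 0.0033 (camera, adjusted p = 0.929). Of 44 chromatin silencing genes, 0 passed either way, with Cbx7 at 0.29 and Dnmt3a at 0.21, a median of 0.0050 and a camera adjusted p of 0.929. Of 34 genes that silence retrotransposons, 0 passed over all genes and 3 adjusted over the list alone, where Ago1 at 0.44 and Tex19.1 at 0.39 rose and Tdrd9, an RNA helicase of the piRNA pathway, fell at -0.41 (limma, adjusted p = 0.0343, 0.0160 and 0.00919 over the list). Their median was 0.032 (camera, adjusted p = 0.492). Spermatid genes (61) had a median of 0.040 (camera, adjusted p = 0.482), with 0 passing either way and Tssk3 at 0.25 and Catsper2 at -0.41.

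The stress and signalling lists did not pass as sets over all probe sets kept. Of 41 immediate early and stress genes, Hmox1 rose over all genes, and adjusted over the list alone Dusp1, a phosphatase of MAP kinases, rose too, at 0.35 (limma, adjusted p = 0.00623 over the list), while Egr1 was at -0.28 (median 0.047; camera, adjusted p = 0.353). This list, immediate early and stress genes, did pass among probe sets above the median level, with a median of 0.11 (camera, adjusted p = 0.0168). Of 27 p53 targets, Trp73 rose over all genes, and Sesn1 at 0.35 rose too adjusted over the list alone (limma, adjusted p = 0.0158 over the list; list median 0.013; camera, adjusted p = 0.814). Of 33 interferon response genes, Ifitm3 rose over all genes, and Irf1 at -0.40, or -0.26 as the mean of its probe sets, fell adjusted over the list alone (limma, adjusted p = 0.0223 over the list; list median 0.043; camera, adjusted p = 0.168).

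The remaining lists did not pass in the main setting. Genes of messenger RNA storage, translation and decay (56) had a median of 0.0067 and a mean of -0.0050, with direction down in the test (camera, adjusted p = 0.929). The RNA-binding protein gene Msi2 at 0.35 rose adjusted over the list alone (limma, adjusted p = 0.0474), and 0 passed over all genes. Igf2bp3 was at -0.36. Glycolysis genes (16) had a median of 0.0067 and a mean of -0.010, with direction down (camera, adjusted p = 0.929), and genes of the 2-cell stage (19) a median of 0.017 (camera, adjusted p = 0.929), with Nelfa at -0.23. Olfactory and vomeronasal receptors (1196) had a median of 0.0033, with direction down (camera, adjusted p = 0.929). Among probe sets above the 25th percentile the receptors did pass, with a median of 0.067 (camera, adjusted p = 0.0170). In these last 3 lists 0 members passed over all genes or adjusted over the list alone.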

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

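Counting repeated probe sets once and the unadjusted threshold near Brwd1 were chosen after seeing the data. Brwd1 kept its direction and its side of the threshold under every alternative, between -4.56 and -4.46, and no gene eligible under the naming rule turned direction. Other genes named here were not part of that check. Past the threshold were 32 probe sets (9 higher, 23 lower). The count was 1 (0 higher, 1 lower) with all probe sets of the table and with repeats counted once, where more tests or fewer low p-values raise the adjustment. With all probe sets the unadjusted limma p-values changed too, that of Brwd1 from 9.4e-11 to 3.6e-10. The count was 76 (27 and 49) with eBayes trend and robust settings, 16 (5 and 11) with the mean of a gene's probe sets, 4 (2 and 2) with a log2 difference of at least 1 and 76 (28 and 48) at an adjusted p under 0.10. The higher count was 15 with probe sets above the median level and 15 with array weights. Leaving out 1 array gave 1 to 18 probe sets, 0 to 7 higher and 1 to 11 lower. With the replicate number as a block the count was 1 (0 higher, 1 lower). Samples with the same number showed little shared deviation (correlations of -0.0015, -0.031 and 0.037), and not every sample correlated best with its own number. With so few samples these correlations cannot exclude that the numbers pair the samples, and the labels do not say.

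The main setting gave 5 passing lists. Above the median level 2 lists passed, histone genes from among the 5 and immediate early and stress genes, which pass nowhere else. Above the 25th percentile 6 passed, the same 5 and the olfactory and vomeronasal receptors. Those receptors are the guide to background, so at the preset correlation camera can also call a small offset of such genes. The count was 1 after quantile normalization again, 1 after cyclic loess, 0 with an estimated correlation, 0 with fry and 3 to 4 without 1 array. Near Brwd1 the count was 0, or 0 to 1 without 1 array and 20 at an unadjusted p. The direction of camera turned for some lists that did not pass in the main setting, and the cause was not tested. That direction is relative to the other genes, so it can turn while the median of a list keeps its sign. Above the median level the median of all tested probe sets was -0.027, against 0.010 in the main setting. The medians of the lists that turned were, above the median level, -0.0083 (zona), -0.013 (maternal effect), 0.010 (RNA storage) and 0.19 (olfactory receptors). Above the 25th percentile they were -0.0067 (2-cell stage) and 0.067 (olfactory receptors), the last with a camera adjusted p of 0.0170. After quantile normalization again they were 0.0047 (zona), -0.0025 (maternal effect), 0.028 (RNA storage), 0.023 (2-cell stage) and 0.0036 (theca). After median centring they were -0.053 (acetylated lysine) and -0.052 (chromatin silencing). After cyclic loess they were 0.022 (zona), 0.012 (maternal effect), 0.018 (meiotic cell cycle), 0.037 (RNA storage), 0.023 (2-cell stage), -0.0032 (theca) and -0.00065 (olfactory receptors). With trend and robust settings it was 0 (zona). With fry, which leaves the medians as in the main setting, they were 0.0067 (RNA storage) and 0.0033 (olfactory receptors). Without 1 array, medians ran from -0.0050 to 0.061 (cohesin), -0.0067 to 0.022 (acetylated lysine), -0.025 to 0.035 (chromatin silencing), -0.0033 to 0.0083 (olfactory receptors), 0 to 0.033 (2-cell stage), -0.0083 to 0.025 (RNA storage), -0.019 to 0.016 (oocyte transcription factors), 0.0050 to 0.043 (p53 targets) and -0.047 to 0.035 (glycolysis). Signal near background, where Brwd1 lies in the mutant, limits how large a fall can be measured.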

Other observations

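The families described here, the macrophage genes, the genes at which wildtype 3 lies with the mutants, the separate test of histone genes and the tests of clustering along chromosomes were chosen after the data were seen. Small nucleolar RNAs were added once their values had been noticed, and narrower keratin and tubulin sets were tried and dropped, so the adjustment over 10 families does not cover every set looked at. Among 10 families looked at, the 77 mitochondrial ribosomal proteins had a median log2 difference of -0.12 (camera, adjusted p = 1.8e-08 over the 10; adjusted p = 0.0702 with an estimated correlation). Of these, 65 were lower and 12 higher, 16 were lower and 0 higher at an unadjusted p under 0.05, and 0 passed over all genes. Mrpl38 was at -0.42, Mrps18a at -0.31 and Mrps5 at -0.29. The family median was -0.093, -0.10 and -0.18 after quantile normalization again, cyclic loess and median centring, and the list passed under each of the 6 omissions of an array (camera, largest adjusted p = 5.7e-06).

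Small nucleolar RNAs, which guide chemical modification of ribosomal RNA and are often made from introns, had a median of -0.097 over 54 genes (camera, adjusted p = 0.0123; adjusted p = 0.445 with an estimated correlation), and the call ended without wildtype 3 (adjusted p = 0.0639) or mutant 3 (0.163). Of these, 30 were lower and 24 higher, 12 were lower and 0 higher at an unadjusted p under 0.05, and 0 passed over all genes. Snord57 was at -1.82 (SE 0.313; limma, adjusted p = 0.122), Snord38a at -1.71 (SE 0.354), Snord33 at -1.24 (SE 0.254) and Snord104 at -1.20 (SE 0.321). These SE are far above the median SE of 0.0811, so the levels varied widely between samples of a group, and the cause was not tested. The sizes for Snord57 and Snord38a are lower limits, since their mutant means of 4.02 and 3.77 lie under the background guide of 4.48. The median was -0.096, -0.11 and -0.15 after quantile normalization again, cyclic loess and median centring.

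The 347 zinc-finger genes named Zfp had a median of -0.033 (camera, adjusted p = 0.00471; adjusted p = 0.0702 with an estimated correlation), with 53 lower and 14 higher at an unadjusted p under 0.05. Their median was -0.037, -0.046 and -0.09 after quantile normalization again, cyclic loess and median centring. A wider set of 413 zinc-finger genes gave a camera adjusted p of 0.00712 and an adjusted p = 0.0939 with an estimated correlation, and its call ended without wildtype 3 (0.0639). The 99 genes with keratin symbols had a median of 0.077 (camera, adjusted p = 0.00584; adjusted p = 0.2998 with an estimated correlation), which was 0.031 with an adjusted p of 0.0593 after cyclic loess. The keratin median was 0.038 after quantile normalization again and 0.02 after median centring. Krt8 was at 0.77 and Krt73 at 1.30, with limma adjusted p-values of 0.136 and 0.186. X-linked genes, proteasome subunits, tubulin symbols and sterol synthesis genes did not pass (camera, adjusted p = 0.838, 0.194, 0.759 and 0.106), and Sqle, an enzyme of sterol synthesis, was at -0.70 (limma, adjusted p = 0.0599).

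Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many as 32 probe sets, the real one, and the highest other gave 1. The splits are too few for a share under 0.05. As a test of strain segments that differ between the pools, of 165 located genes with a limma p under 0.001, 56 lay within 2 Mb of another, against 42 to 73 in the central 95% of 10000 random draws. This decides nothing either way.

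As a test of a difference between arrays that depends on intensity, the median difference of all genes ran from 0.077 in the fifth of 10 bins of level to -0.067 in the eighth. Of the 5 lists, 1, that of histone genes, passed after cyclic loess (camera, adjusted p = 0.0229) and lay below all 10000 random lists of like level. This argues against such a trend as its whole cause, with a limit. The random lists drew genes singly, so their spread is too narrow if histone genes move together. With an estimated correlation the histone list did not pass on the deposited values (camera, adjusted p = 0.584). Among such random lists oxidative phosphorylation lay at percentile 0.72, outside the central 95%, while ribosomal proteins at 3.78, DNA repair at 3.86 and immune markers at 84.3 lay inside. After cyclic loess oxidative phosphorylation kept 64.1% of its median, DNA repair 80.4%, ribosomal proteins 43.1% and immune markers 33.9%, all without passing, so an intensity-dependent difference may account for part of these 4 shifts and is not excluded. Only 1 list passed under all 6 omissions of a single array, but lost calls alone do not point to a single array, since every median kept its sign and some, such as that of immune markers (0.054 to 0.10), stayed near or above their full value, while DNA repair was at -0.023 without mutant 2. For lists, 1 of the 10 splits gave 5, the real one, and the highest other gave 3, again too few splits for a share under 0.05.

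Macrophage RNA in the mutant samples is a candidate source of the C1qb difference of 0.90 and of the higher immune list. The 23 other genes of a macrophage list had a median of 0.13 (bootstrap 95% interval 0.053 to 0.17), 21 of them higher. With C1qb included, the 24 passed as a set at a median of 0.14 (camera, adjusted p = 0.000424; adjusted p = 0.0702 with an estimated correlation). That set holds C1qb itself and was chosen after the data were seen, so its call is not separate support. The median of the 24 was 0.078 after cyclic loess, 0.084 after quantile normalization again and 0.082 after median centring. Of the 23, 14 lay at or under 4.48, the 95th percentile of the receptor probe sets, in both groups, among them the abundant macrophage genes Lyz2 at 0.0033 and Cd74 at a level of 3.49 in both. The 9 above it ran from -0.070 for Cd68 to 0.34 for Laptm5, all below C1qb, and the partner subunits C1qa and C1qc were at 0.18 (95% confidence interval 0.0089 to 0.34) and 0.063 (-0.17 to 0.30), which gives them no rise like that of C1qb. C1qc lay under the guide and C1qa just above it (4.52 and 4.70), and genes near background cannot exclude a small amount of macrophage RNA, so it stays open.

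Wildtype 3 lay within 0.3 log2 units of the range of the mutants, and with them at least 0.8 from the other wildtype samples, at 19 genes, among them Tex15, Parp8, Htr5a and Pde6b, against 1 to 4 such genes for each other array. Rnase6 had 8.26, 7.75 and 4.80 in wildtype 1, 2 and 3 and 6.38, 4.89 and 4.67 in the mutants, and Plin2, a lipid droplet protein, 7.86, 7.76 and 6.17 against 6.28, 5.90 and 5.99. A mislabelled mutant sample is excluded by Brwd1, which was 8.98 on wildtype 3. Strain segments may differ between the pools, but 1 pair of these genes lay 1 to 10 Mb apart, against a median of 1 in random draws, while the only 2 such genes of wildtype 1 formed a pair, against 0 in the central 95% of draws, and among the 200 genes with the largest deviation of wildtype 3 there were 207 such pairs, against 135 to 202 in the central 95% of random draws. The same count was 159 to 194 for the 5 other arrays and 187 for the difference between the groups, all inside, so the excess is small, in 1 of 7 counts, and strain segments stay open.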
